A study of Homo sapiens with 10 samples.

How the data were processed

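RNA was measured by sequencing in 10 samples of HaCaT cells, a human keratinocyte line whose source the labels give as mucosa. Per the labels' protocols, total RNA was extracted with Trizol, cDNA was amplified by PCR, and the products were circularised with a splint oligonucleotide to make the libraries. Samples were assigned to the groups vehicle, LBP, irradiated vehicle and irradiated LBP from their labels alone. The submitters' processing notes name HISAT2 and the build GRCh38 without versions, and the counting tool, its strand setting and its annotation are not given in the sources used here. The count table, as deposited by the authors, holds whole-number counts per gene for the 10 samples, and the FPKM table, also deposited by the authors, holds the same genes scaled by gene length and library size. No column belonged to any other sample.

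The count table has 22003 features, of which 2071 carry names of assembled loci without an annotated gene and 2880 have no count in any library. The assembled loci held 0.911 ± 0.022% (SD, n = 2) to 0.977 ± 0.034% (SD, n = 3) of counts by group and 1288 of them were tested. Low counts were more often even than odd, with 6040 values equal to 2 against 1398 equal to 1 and 3256 equal to 3, and 59.7% of counts from 1 to 10 were even. Counts may therefore include both mates of some read pairs, which makes counting error larger than the counts alone imply. Depth ran from 31830506 to 62986831 counts per library. Replicate libraries differed by more than counting noise in every group, with a chi-square per degree of freedom from 10.7 to 36.8, so none was treated as a repeat of another library's data. Libraries of different groups with the same replicate number were not paired, because nothing in the labels says that a number marks a shared culture or day. Not every same-numbered pair was positively correlated, but with so few libraries per group this cannot exclude a shared culture or day.

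Counts were tested with edgeR 4.0.16 in R 4.3.3. Features were kept by filterByExpr with a minimum count of 10, which left 14799. Libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model (glmQLFit and glmQLFTest) with 1 mean per group was fitted to all 10 libraries, so that the groups shared 1 estimate of spread with 6 residual degrees of freedom and a prior of 6.06. The 4 comparisons between groups and the interaction, which is the LBP effect in irradiated cells minus that in non-irradiated cells, were tested as contrasts. P-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. CPM are scaled by TMM. Every adjusted p for a gene comes from this test unless another tool is named.

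In all, 31 gene lists were fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for naming genes, except where a choice is said to have been made later. They cover p53 targets, G2 and mitosis, S phase, histones, 2 kinds of double-strand break repair, apoptosis, NF-kB and cytokines, interferon, NRF2, integrated stress response, unfolded proteins, heat shock, immediate early and ERK genes, basal, differentiating and activated keratinocytes, matrix remodelling, hypoxia and glycolysis, cholesterol, autophagy, Notch, ribosomal proteins, the respiratory chain, mitochondrially encoded genes and markers of 5 other kinds of cell. The 28 lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the Benjamini-Hochberg method over the lists of a comparison. Camera with an estimated correlation and fry stand beside it. Camera compares a list with all other genes; fry asks whether the genes of a list move, on balance, to 1 side. For the lists that camera called, the median, the mean and the direction of the test had the same sign in every comparison; among lists not called they differed in several, such as the NF-kB, apoptosis and Notch lists with LBP in irradiated cells.

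Where the number of alternative settings that lost a call is given for a gene, the 2-fold minimum is left out. By the naming rule, each comparison between groups gives the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1, a gene symbol that is not a clone, antisense or pseudogene name, and groups that do not overlap. It adds a fixed set, which includes CDKN1A, MDM2, GDF15, ATF3, GADD45A, HMOX1, NQO1, IL6 and CXCL8, and up to 4 members of each list with the smallest p. Positions and gene types come from GENCODE v29 on GRCh38, in which 19414 symbols of the table (97.4% of those with gene names) had 1 position. For features with 0 counts in every library of a group, folds are lower bounds against 3 counts per library, and also against 6, a floor added after the data were seen for the case that both mates of each pair were counted. Values for some of the genes that the rule names are not reported here.

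The tests were run on simulated counts drawn from the means and library sizes of these samples, with each gene's spread taken from its trend over expression level. The changed genes were drawn from those above a minimum level. Recovery is therefore no measure for genes that vary more than the trend or have low levels. Of 67 genes changed by 1.5-fold, 74.6% were recovered for irradiation without LBP (14595 genes tested), 82.1% for LBP in irradiated cells (14601 genes), 52.2% for LBP in non-irradiated cells (14620 genes), 71.6% for irradiation with LBP (14596 genes) and 46.3% for the interaction (14579 genes). Of 67 genes changed by 2-fold, 92.5%, 95.5%, 92.5%, 94.0% and 83.6% were recovered in the same order. False calls made up 12 of 190, 6 of 191, 7 of 169, 13 of 190 and 4 of 157 calls in that order.

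Agreement of effects between comparisons was measured by correlations across genes and by the overlap of calls against n1 × n2 / N for independent lists, with an SE from leaving out each library. The share of irradiation changes with the opposite sign under LBP was also computed in 50 simulations of unchanged groups that share the irradiated vehicle libraries.

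The alternatives were relative log expression (RLE) factors in place of TMM, DESeq2 1.42.0 with its own size factors, no filter on low counts, a mean CPM of at least 1, models with only the groups compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 and on every feature with any FPKM, a 2-fold minimum, and leaving out each replicate in turn. After seeing the data, 2 more were added: removal of a smooth trend of each library on gene length, and leaving out LBP replicate 2 and irradiated vehicle replicate 3 together, the libraries with the most negative length trends. Gene length was taken from the ratio of counts to FPKM for 12833 tested genes. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.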

Results

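RNA sequencing was carried out on HaCaT cells, a spontaneously immortalised human keratinocyte line. Cells received LBP, a polysaccharide-glycoprotein preparation from the goji plant Lycium barbarum, or vehicle for 24 h and were then left alone or exposed to 12 Gy of ionising radiation. RNA was collected 3 h after exposure. The 10 libraries formed 4 groups: vehicle (n = 2), LBP (n = 2), irradiated vehicle (n = 3) and irradiated LBP (n = 3). The labels number the libraries of a group as repeats of the experiment, and nothing says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Total counts were 38107258 and 62986831 in the vehicle libraries, 40673084 and 44495984 in the LBP libraries, 39999300, 46466567 and 54318209 in the irradiated vehicle libraries and 47950059, 31830506 and 43814878 in the irradiated LBP libraries. A count of 0 in such a library allows a level of up to 0.0476 to 0.0942 CPM (counts scaled to the size of the library), taking 3 counts as the limit and covering counting error only. If both mates of each read pair were counted, the limit is 6 counts, or 0.0953 to 0.188 CPM. Of the 22003 features in the table, 14799 were tested, and the fitted coefficient of variation between libraries of a group was 11.5%. Values are log2 fold changes ± standard error (SE) unless another unit is named, and levels are CPM ± standard deviation (SD). Along the principal component with the largest share of variance (19.4%), the LBP and vehicle libraries separated.

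The comparison of irradiated with non-irradiated vehicle cells asked what 12 Gy did to the keratinocytes within 3 h (n = 3 against 2). Genes of late G2 and mitosis fell. AURKA, a kinase of spindle pole maturation, fell from 203 ± 4.1 to 86.0 ± 5.5 CPM, a change of -1.24 ± 0.09 (adjusted p = 0.00016). PIF1, a DNA helicase whose transcript peaks in G2, changed by -1.78 ± 0.16, from 13.1 to 3.79 CPM (adjusted p = 0.00036). CCNF, encoding cyclin F, changed by -1.11 ± 0.09, and PLK1, a kinase needed for mitotic entry, fell from 249 to 124 CPM. KIF18A, FAM83D, GTSE1, PSRC1, CENPE and GAS2L3, all with roles at the spindle, kinetochore or cytoskeleton of dividing cells, completed the 10 lowest by the naming rule, with changes from -1.24 for PSRC1 to -0.90 for GAS2L3. The calls of PSRC1, PLK1, CENPE and GAS2L3 were lost in 5, 3, 7 and 9 of 16 alternative settings. AURKA lies on chromosome 20 at 56369389 to 56392337 on the minus strand, PIF1 on chromosome 15 at 64815632 to 64825668 on the minus strand, CCNF on chromosome 16 at 2429394 to 2458854 on the plus strand and PLK1 on chromosome 16 at 23677656 to 23690367 on the plus strand. These are GRCh38 positions, and all 4 genes are annotated as protein coding.

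After irradiation without LBP 5 features rose, of which 4 are described. JUND, a member of the AP-1 family of transcription factors, rose from 18.1 ± 2.4 to 36.6 ± 0.68 CPM, a change of 1.01 ± 0.19 (adjusted p = 0.042). It is a protein-coding gene on chromosome 19 at 18279760 to 18281622. UGT1A1, a glucuronosyltransferase, changed by 0.95 ± 0.17 (adjusted p = 0.027). UGT1A1 overlaps other genes of the UGT1A family on its strand, so how reads were divided among them is uncertain. AC135050.2 and AC008982.1 were named after their values were seen. Both had 0 counts in both vehicle libraries and were at least 40.9-fold and at least 9.81-fold higher in the irradiated vehicle libraries against a floor of 3 counts per library, or at least 20.4-fold and at least 4.91-fold if both mates were counted. Both overlap other genes on the same strand. JUND and UGT1A1 lost their calls in 9 and 7 of 16 alternative settings.

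By the gene lists fixed in advance, 24 of the 35 G2 and mitosis genes fell and none rose; 32 fell when adjusted over the list alone, and all 35 had negative values, with a median of -0.55. Besides the genes above, CENPF, ASPM, MKI67 and CCNB1 were among those that fell. Camera called the list lower against other genes (adjusted p = 4.0e-166), and the call held with an estimated correlation (adjusted p = 0.000995) and with fry (adjusted p = 0.00034). None of the 22 replication-dependent histone genes passed over all genes. Among them, 1 fell when adjusted over the list alone. The histone list had a median of -0.46 (camera adjusted p = 1.9e-05; adjusted p = 0.11 with an estimated correlation), and H2AC6 had a value of -0.54 ± 0.13. The list lies at low levels, which limits this result. Of its 37 members in the table, 12 had a mean of at least 1 CPM, and the highest, H1-2, had 8.92 CPM (without TMM scaling).

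None of the 31 tested p53 target genes passed, over all genes or when adjusted over the list alone, and their median was 0.095 (camera adjusted p = 0.063; 0.70 with an estimated correlation). With the length trend removed, a setting added after the data were seen, the median was 0.10. Camera called the list in that setting (adjusted p = 0.018, and 0.57 with an estimated correlation). CDKN1A, the p21 cell cycle inhibitor, had 118 CPM in vehicle and 145 CPM in irradiated vehicle cells, a difference of 0.30 ± 0.21 (adjusted p = 0.84). MDM2, which encodes a ubiquitin ligase, stood at -0.02 ± 0.08, GDF15 at 0.53 ± 0.79 and GADD45A at 0.61 ± 0.22. The limits of this result are the SEs: a change of CDKN1A of the size seen for AURKA would have been several SEs from 0.

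Among other lists, camera called the immediate early genes higher (median 0.33, adjusted p = 1.1e-07; adjusted p = 0.70 with an estimated correlation), and with them the ERK pathway targets (adjusted p = 1.9e-05; 0.70 with an estimated correlation), the NF-kB and inflammatory cytokine genes (adjusted p = 0.00025; 0.80 with an estimated correlation), the DNA replication and S phase genes (adjusted p = 0.0053; 0.80 with an estimated correlation) and the matrix remodelling genes (adjusted p = 0.0053; 0.75 with an estimated correlation). It called the interferon-stimulated genes (adjusted p = 7.6e-05; 0.75 with an estimated correlation) and the heat shock genes (adjusted p = 0.0024; 0.70 with an estimated correlation) lower. No member of these lists passed over all genes, and when adjusted over the list alone only 1 S phase gene did. Values for single members were 1.12 ± 0.42 for FOSB, 0.54 for JUN, 0.78 ± 0.19 for the cyclin E gene CCNE2, 1.54 ± 0.66 for the chemokine CXCL2, 0.87 ± 0.49 for CXCL8, 0.33 ± 0.40 for IL6, 0.29 ± 0.50 for ATF3 and -0.41 for IFIT2.

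No member passed in the remaining lists, over all genes or when adjusted over the list alone, and camera called none of them. Its adjusted p was 0.81 for the homologous recombination and Fanconi genes, 0.50 for the end joining genes, 0.065 for the apoptosis regulators, 0.87 for the NRF2 antioxidant genes, 0.24 for the integrated stress response genes and 0.27 for the unfolded protein genes of the endoplasmic reticulum. It was 0.94 for the basal keratinocyte genes, 0.97 for the differentiation genes, 0.50 for the activation keratins and alarmins, 0.90 for the hypoxia and glycolysis genes, 0.87 for the cholesterol genes, 0.97 for the autophagy genes and 0.97 for the Notch genes. It was 0.81 for the cytosolic ribosomal protein genes, 0.52 for the respiratory chain genes, 0.22 for the mitochondrially encoded genes, 0.97 for leukocyte markers and 0.29 for simple and mucosal epithelial markers. Of the fibroblast, endothelial and melanocyte markers, 4, 2 and 2 were tested, too few for a list test, and none passed.

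In total 65 features changed after irradiation without LBP, 5 higher and 60 lower, by edgeR's quasi-likelihood test, and 14 of them changed by at least 2-fold. All 65 had groups that did not overlap, against 27.6% of all genes, where chance gives 20% for 3 against 2. Calls are chosen by the same difference in the same libraries, so this share adds no support to them, here or in the later comparisons. The split was 35 higher and 94 lower with DESeq2, 129 in total, and the count was 109 with only the 2 groups compared in the model and 43, 42 and 21 with limma on the FPKM values. It was 28 and 25 without vehicle replicate 1 or 2, and 32, 33 and 35 without irradiated vehicle replicate 1, 2 or 3.

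**Figure D1:**
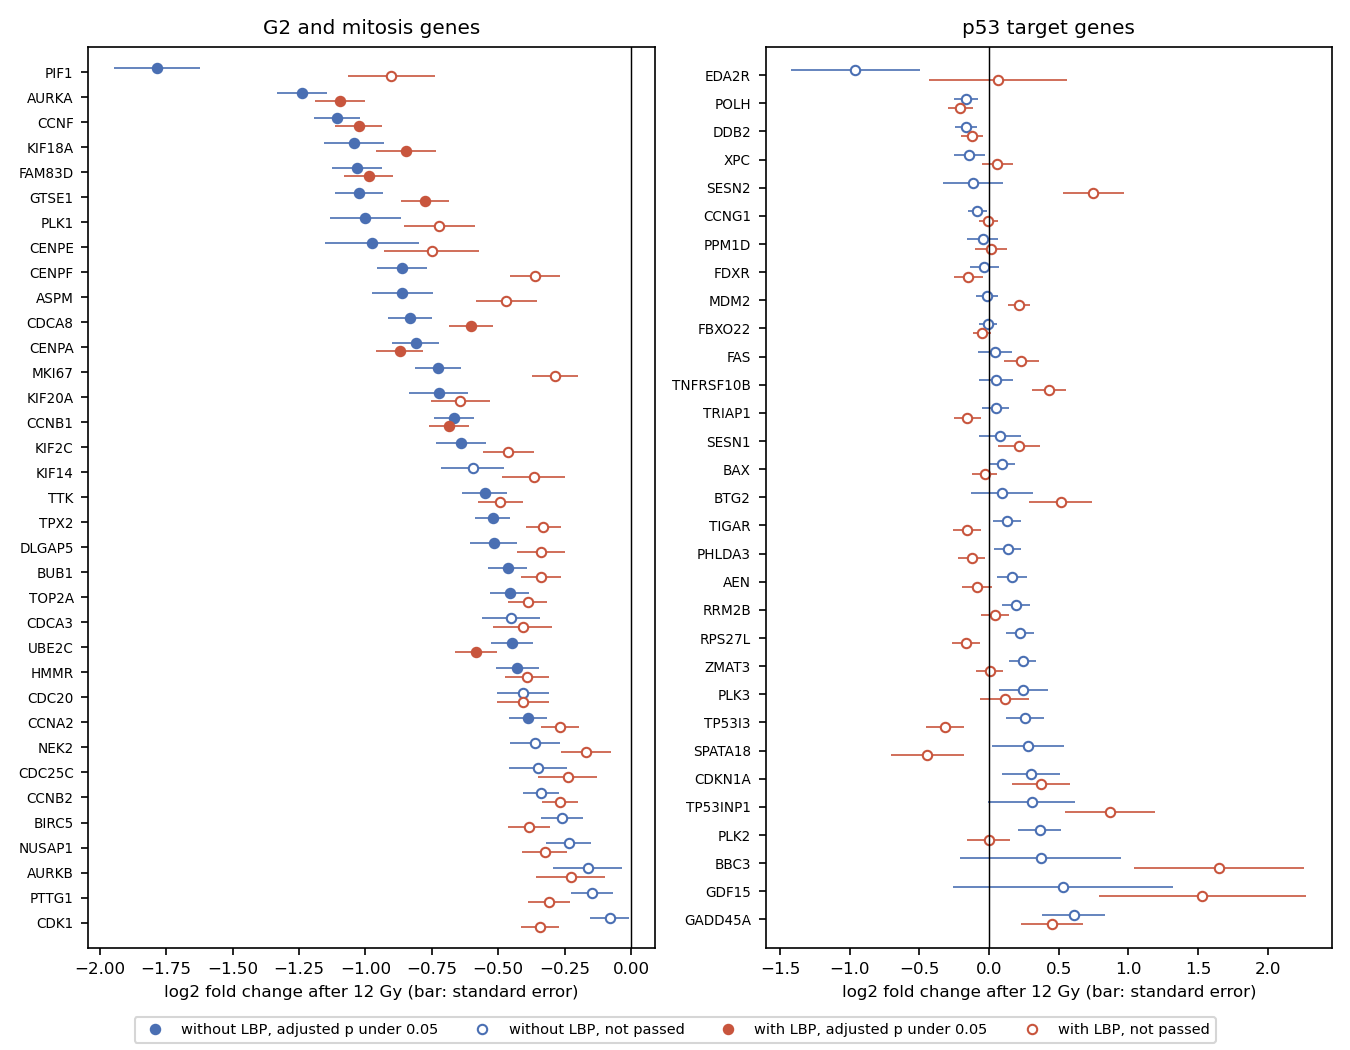
Log2 fold changes after 12 Gy without LBP (blue) and with LBP (red) for each tested gene of the G2 and mitosis list and the p53 target list, with bars for the SE and filled points for an adjusted p under 0.05. All 35 G2 and mitosis genes lie below 0 without LBP, with a median of -0.55, whereas the p53 targets have a median of 0.095 and no filled point.

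The comparison of irradiated LBP with irradiated vehicle cells asked what LBP pretreatment did to cells that were then irradiated (n = 3 against 3). HMOX1, encoding the haem-degrading enzyme haem oxygenase, was the highest by the naming rule and rose 18.8-fold, from 4.87 ± 1.1 to 92.3 ± 19 CPM, a change of 4.24 ± 0.20 (adjusted p = 5.1e-07). CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, rose 9.04-fold, from 10.8 to 98.2 CPM, and CYP1B1, another target of that receptor, changed by 2.41 ± 0.12, from 25.6 to 137 CPM. The aldo-keto reductase genes AKR1C2, AKR1C1 and AKR1C3 changed by 2.42 ± 0.14, 2.37 ± 0.15 and 2.05 ± 0.13. NQO1, a quinone reductase and standard NRF2 target, changed by 1.03 ± 0.08, from 258 to 526 CPM (adjusted p = 4.5e-05). CYP4F3, CYP4F11, ALDH3A1 and the growth factor gene EPGN completed the 10 highest by the naming rule, with changes of 2.13 ± 0.26, 1.87 ± 0.12, 1.84 ± 0.13 and 2.00 ± 0.17. AC008982.1, outside that rule and named after its values were seen, was at least 8.34-fold lower against a floor of 3 counts per library (at least 4.17-fold if both mates were counted), with 0 counts in all 3 irradiated LBP libraries.

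The 10 lowest with LBP in irradiated cells, by the naming rule, included the chemokine genes CXCL6 and CXCL1. CXCL6 fell from 15.6 to 5.78 CPM, a change of -1.44 ± 0.12 (adjusted p = 4.5e-05), and CXCL1 changed by -1.47 ± 0.31 (adjusted p = 0.023), a call lost in 5 of 17 alternative settings. VIM, the intermediate filament of mesenchymal cells, fell from 17.2 to 8.61 CPM (adjusted p = 0.00090). MYL9, a myosin light chain, changed by -0.90 ± 0.15, and PRICKLE1, of planar cell polarity, by -1.12 ± 0.15. FILIP1L, NEXN, DACT1, ZFP57 and PLEKHO1 had changes from -1.30 for FILIP1L to -0.87 for PLEKHO1. Calls were lost in 7 of 17 settings for NEXN, 6 for ZFP57, 3 for MYL9 and 1 for FILIP1L, and in 5 and 7 of 15 for DACT1 and PLEKHO1.

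HMOX1 (ENSG00000100292.16) lies on chromosome 22 at 35380361 to 35394214 on the plus strand, CYP1A1 on chromosome 15 at 74719542 to 74725610 on the minus strand, CYP1B1 on chromosome 2 at 38066973 to 38109902 on the minus strand and NQO1 on chromosome 16 at 69706996 to 69726951 on the minus strand. AKR1C1, AKR1C2 and AKR1C3 lie side by side on chromosome 10, at 4963253 to 4983283, 4987400 to 5018031 and 5035354 to 5107686. They are close paralogs, so the division of reads among them is uncertain. CXCL6 and CXCL1 are neighbours on chromosome 4, at 73836497 to 73849064 and 73869393 to 73871242, and VIM lies on chromosome 10 at 17228259 to 17237593, these 3 on the plus strand. All are annotated as protein coding in GRCh38.

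Of the 27 NRF2 antioxidant genes, 23 rose with LBP in irradiated cells and none fell; 24 rose when adjusted over the list alone. NRF2 is the transcription factor that drives genes of glutathione, thioredoxin and iron handling. The median was 0.76 (camera adjusted p = 1.8e-108; adjusted p = 0.0072 with an estimated correlation; fry adjusted p = 0.00091), so the call held under all 3 tests. Examples besides those above were SLC7A11, the cystine importer, which rose from 97.4 to 269 CPM, a change of 1.47 ± 0.14. SLC7A11 is also in the list of integrated stress response and ATF4 genes. There 13 of 29 rose and none fell, with 21 higher when adjusted over the list alone, a median of 0.54 and a camera adjusted p of 3.0e-23 (adjusted p = 0.12 with an estimated correlation; fry adjusted p = 0.021). ASNS, asparagine synthetase, changed by 0.68 ± 0.07, and the amino acid transporter subunits SLC3A2 and SLC7A5 by 0.70 ± 0.07 and 0.52 ± 0.07.

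Of the 24 hypoxia and glycolysis genes, 8 rose and none fell, 12 when adjusted over the list alone (median 0.34, camera adjusted p = 9.1e-19; adjusted p = 0.081 with an estimated correlation; fry adjusted p = 0.0060). ALDOC, an aldolase, changed by 1.11 ± 0.09, BNIP3, of mitochondrial clearance, by 1.25 ± 0.12 and NDRG1 by 1.05 ± 0.10. CA9, a carbonic anhydrase and standard target of HIF, changed by 2.70 ± 0.33 but at low levels, from 0.345 to 2.26 CPM.

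Smaller parts of other lists rose with LBP in irradiated cells. Of 23 keratinocyte differentiation genes 4 rose, 6 when adjusted over the list alone: the cornified envelope genes FLG (1.06 ± 0.17), TGM1 (0.87) and SPRR2A (0.76), and SERPINB3 (0.91). Camera gave the list an adjusted p of 0.022 (adjusted p = 0.68 with an estimated correlation). Of 18 basal keratinocyte genes 3 rose, 6 when adjusted over the list alone: TP63 (0.41), EGFR (0.41) and the laminin gene LAMB3 (0.46), with a camera adjusted p of 0.00020 (adjusted p = 0.54 with an estimated correlation). Of 23 immediate early genes 3 rose, FOSB (1.66 ± 0.34), EGR1 (1.55 ± 0.33) and KLF10 (0.81 ± 0.17), 12 when adjusted over the list alone (camera adjusted p = 8.1e-06; adjusted p = 0.68 with an estimated correlation). EGR1 and the growth factor gene EREG (1.36 ± 0.34) were the 2 of 19 ERK targets that rose, 4 when adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.78 with an estimated correlation). Of 18 autophagy and lysosome genes, SQSTM1 (0.54), CTSD (0.51) and CTSL (0.38) rose, 4 when adjusted over the list alone (camera adjusted p = 0.0027; adjusted p = 0.54 with an estimated correlation). Of 17 alternative settings, the call of EREG was lost in 10, those of SPRR2A and LAMB3 in 8, EGR1 in 7, SERPINB3, EGFR, FOSB and KLF10 in 6, TP63 in 5, TGM1 in 4, CTSL in 3, FLG in 2 and CTSD in 1.

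Camera called 5 lists lower with LBP in irradiated cells. CHORDC1 (-0.44) and HSPE1 (-0.35) were the 2 of 18 heat shock genes that fell, also 2 when adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.54 with an estimated correlation). Of 35 G2 and mitosis genes 1 fell, PTTG1 (-0.29), and 2 when adjusted over the list alone (median -0.10, camera adjusted p = 0.0066; adjusted p = 0.78 with an estimated correlation). None of 36 S phase genes passed either way (camera adjusted p = 0.00012; adjusted p = 0.68 with an estimated correlation). None of 33 ribosomal protein genes did (camera adjusted p = 0.0061; adjusted p = 0.78 with an estimated correlation). Of 30 respiratory chain genes 1 fell, UQCRB (-0.28), and none when adjusted over the list alone (camera adjusted p = 0.0066; adjusted p = 0.78 with an estimated correlation). The calls of PTTG1 and UQCRB were each lost in 11 of 17 alternative settings. The ribosomal and respiratory lists hold short transcripts, and the libraries differed in a trend on gene length: the Spearman correlation of a library's deviations with gene length ran from -0.46 in LBP replicate 2 and -0.26 in irradiated vehicle replicate 3 to 0.26 in irradiated LBP replicate 1. With that trend removed, a setting chosen after seeing the data, the medians of the ribosomal and respiratory lists went from -0.091 and -0.093 to -0.016 and -0.0094.

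The 13 mitochondrially encoded genes, listed as a sign of RNA quality, had a camera adjusted p of 0.034 on the higher side (adjusted p = 0.78 with an estimated correlation), with none passing alone. They held 2.66 ± 0.70% of counts in irradiated vehicle libraries and 3.06 ± 0.22% in irradiated LBP libraries. The remaining lists were not called with LBP in irradiated cells. Of the p53 targets SESN2 rose (0.97 ± 0.19) and RPS27L (-0.40) and CCNG1 (-0.24) fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.67), and CDKN1A stood at 0.46 ± 0.18 (adjusted p = 0.18). Among genes of repair and cell death, XRCC4 (-0.44), RAD54B (-0.48) and BIK (-0.52) fell and DCLRE1C (0.37) rose. The interferon-induced chemokine CXCL10 fell, from 0.757 to 0.278 CPM, and so did IFIT5 (-0.29), the Notch pathway genes DLL1 (-0.36), MAML2 (-0.44) and LFNG (-0.44), KRT18 (-0.36) and MITF (-0.46). XBP1 (0.37) and MUC1 (0.58) rose. Of 17 alternative settings, the call of DCLRE1C was lost in 13, those of CCNG1 and IFIT5 in 12, BIK and LFNG in 9, RPS27L and XBP1 in 8, MAML2 in 7, XRCC4 in 5 and SESN2, RAD54B and DLL1 in 4, and that of CXCL10 in 9 of 14. IL6 stood at 0.97 (adjusted p = 0.13), CXCL8 at -0.46, GDF15 at 1.77 ± 0.65 (adjusted p = 0.14), ATF3 at 1.39 (adjusted p = 0.097), MDM2 at 0.11 and GADD45A at 0.22. None of these 6 passed.

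In total 645 features changed with LBP in irradiated cells, 413 higher and 232 lower, and 77 changed by at least 2-fold, 62 of them higher. Of the 645, 644 had groups that did not overlap, against 27.5% of all genes, where chance gives 10% for 3 against 3. The count was 1228 with DESeq2, 409 with only these 2 groups in the model, and 388, 382 and 169 with limma on the FPKM values. It was 195, 176 and 223 without irradiated vehicle replicate 1, 2 or 3, 393 and 420 without irradiated LBP replicate 1 or 3, and 150 without both LBP replicate 2 and irradiated vehicle replicate 3, a setting chosen after seeing the data.

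**Figure D2:**
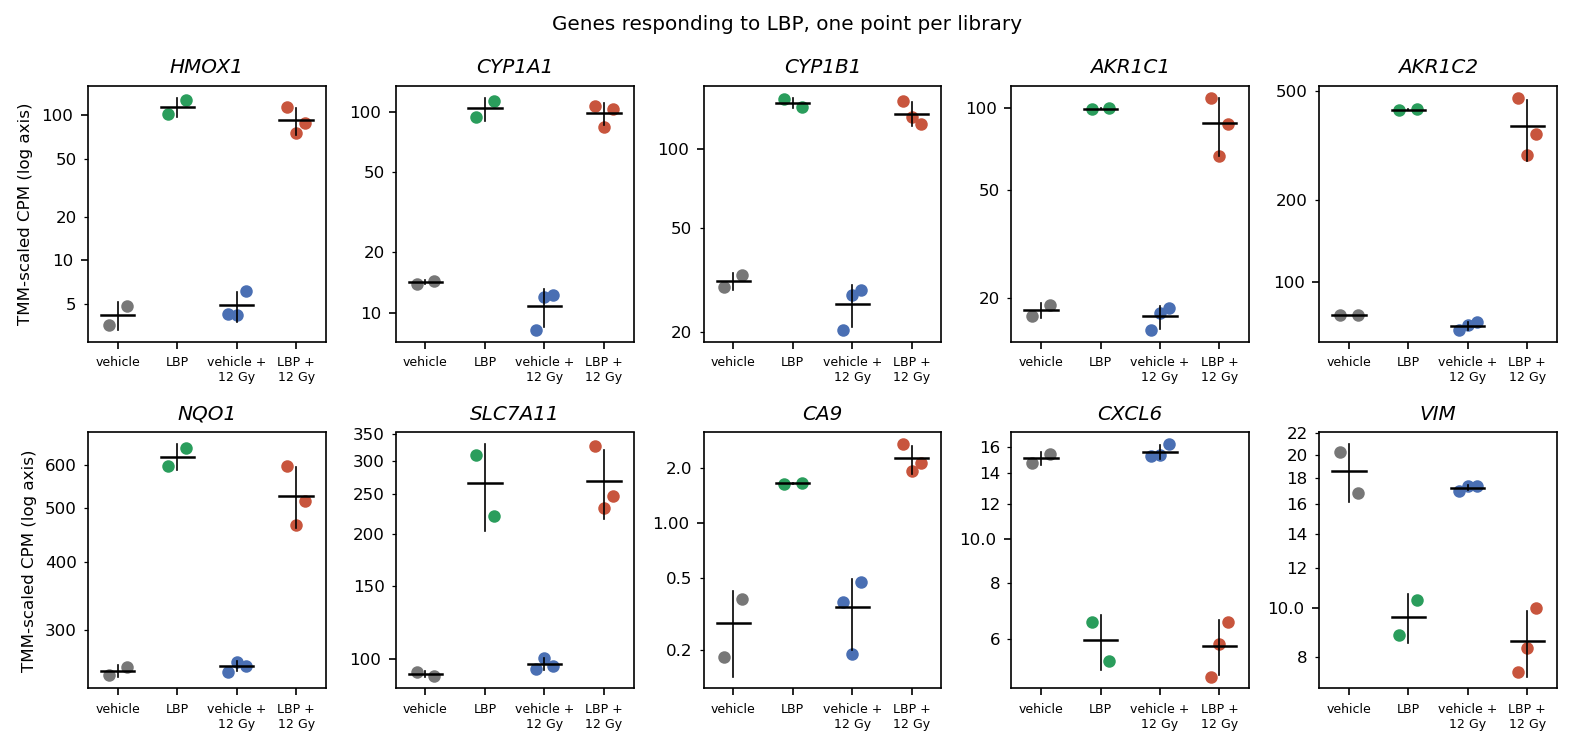
TMM-scaled CPM per library on a log axis for 10 genes that changed with LBP in both comparisons, with a line for the mean of the group and a bar for its SD. HMOX1 has means of 4.20 CPM in vehicle, 115 CPM in LBP, 4.87 CPM in irradiated vehicle and 92.3 CPM in irradiated LBP libraries.

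The comparison of LBP with vehicle in non-irradiated cells asked what LBP did on its own (n = 2 against 2). HMOX1 rose from 4.20 ± 0.91 to 115 ± 17 CPM, a change of 4.75 ± 0.25 (adjusted p = 2.9e-06). CYP1A1 changed by 2.87 ± 0.18, from 14.2 to 104 CPM, and CYP1B1 by 2.26 ± 0.15. AKR1C2, AKR1C1 and AKR1C3 changed by 2.50 ± 0.17, 2.47 ± 0.18 and 2.18 ± 0.16. EPGN, ALDH3A1, the NRF2-induced oxidative stress gene OSGIN1 and the aldo-keto reductase gene AKR1B10 completed the 10 highest, with changes from 2.26 for EPGN to 1.86 for AKR1B10. NQO1 changed by 1.29 ± 0.10, from 253 to 619 CPM.

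CXCL6 changed by -1.35 ± 0.14 and VIM by -0.95 ± 0.14 with LBP in non-irradiated cells. The lowest by the naming rule was ZBED6, which changed by -2.19 ± 0.32, from 85.4 to 18.8 CPM (adjusted p = 0.0063). ZBED6 lies at 203795714 to 203854999 on chromosome 1 within ZC3H11A on the same strand, and ZC3H11A stood at 1.05 ± 0.22 (adjusted p = 0.055), so the reads of this pair may have been divided differently between libraries. DACT1, the protocadherin gene PCDHAC2, SYT16, FGD3, the talin gene TLN2, PRICKLE1 and PGM2L1 completed the 10 lowest, with changes from -1.22 for DACT1 to -0.92 for PGM2L1. Calls were lost in 4 of 15 alternative settings for ZBED6 and VIM, 7 for TLN2 and 8 for PRICKLE1, and of 13 settings in 7 for PCDHAC2, 6 for DACT1, FGD3 and PGM2L1 and 5 for SYT16. CXCL1 stood at -1.49 ± 0.38 (adjusted p = 0.11) and CDKN1A at 0.38 ± 0.23, and neither passed.

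Of the 27 NRF2 genes, 20 rose in non-irradiated cells and none fell, and all 27 rose when adjusted over the list alone. The median was 0.94 (camera adjusted p = 1.4e-142; adjusted p = 0.0029 with an estimated correlation; fry adjusted p = 0.00079). Of 29 integrated stress response genes 7 rose, 11 when adjusted over the list alone (camera adjusted p = 3.3e-16; adjusted p = 0.23 with an estimated correlation). Among them were ASNS (0.79), SLC7A11 (1.53), SLC3A2 (0.60) and PHGDH (0.54), the last an enzyme of serine synthesis. Of 24 hypoxia and glycolysis genes 5 rose, 8 when adjusted over the list alone, with ALDOC at 1.07, BNIP3 at 1.35, NDRG1 at 1.01 and CA9 at 2.47 (camera adjusted p = 1.1e-15; adjusted p = 0.13 with an estimated correlation; fry adjusted p = 0.023). KRT16, a keratin of activated keratinocytes, rose by 1.27 ± 0.18, alone of 13 activation keratins and alarmins, with 4 higher when adjusted over the list alone (camera adjusted p = 0.00010; adjusted p = 0.27 with an estimated correlation). KRT10, a keratin of differentiating cells, rose by 0.50, alone of 23 differentiation genes, with 3 when adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.45 with an estimated correlation). SQSTM1 (0.68) rose, and FN1, encoding fibronectin (-0.80 ± 0.16), and MAML2 (-0.66) fell, in lists that camera did not call. Of 15 alternative settings, the call of MAML2 was lost in 8, that of PHGDH in 7, SLC3A2 in 6, KRT10, SQSTM1 and FN1 in 5, KRT16 in 4 and NDRG1 in 1, and that of CA9 in 5 of 13.

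None of the 35 G2 and mitosis genes passed over all genes with LBP in non-irradiated cells, but 6 fell when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 4.0e-10; adjusted p = 0.27 with an estimated correlation). Camera also called the immediate early genes (adjusted p = 4.8e-05; 0.83 with an estimated correlation) and the ERK targets (adjusted p = 0.025; 0.84 with an estimated correlation) higher and the NF-kB and cytokine genes lower (adjusted p = 0.040; 0.87 with an estimated correlation). It called the ribosomal protein genes (median 0.14, adjusted p = 6.2e-06; 0.81 with an estimated correlation) and the respiratory chain genes (median 0.12, adjusted p = 0.00076; 0.83 with an estimated correlation) higher, and these medians went to 0.022 and 0.029 with the length trend removed. It called the mitochondrially encoded genes lower (median -0.28, adjusted p = 0.0045; 0.84 with an estimated correlation), which held 2.76 ± 0.30% of counts in vehicle and 2.25 ± 0.23% in LBP libraries.

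In total 119 features changed with LBP in non-irradiated cells, 80 higher and 39 lower, and 42 changed by at least 2-fold, 34 of them higher. All 119 had groups that did not overlap, against 45.5% of all genes, where chance gives 33.3% for 2 against 2. The split was 191 higher and 183 lower with DESeq2, 374 in total; the count was 188 without a filter on low counts, 278 with only these 2 groups in the model, and 79 and 45 with limma on log2(FPKM + 0.1) and on every feature with any FPKM. It was 38 and 42 without vehicle replicate 1 or 2, 52 and 46 without LBP replicate 1 or 2, and 34 without both LBP replicate 2 and irradiated vehicle replicate 3.

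The comparison of irradiated with non-irradiated LBP cells asked what 12 Gy did to cells that had received LBP (n = 3 against 2). AURKA fell from 167 ± 21 to 78.2 ± 6.9 CPM, a change of -1.10 ± 0.09 (adjusted p = 0.00022). CCNF changed by -1.03 ± 0.09 and CCNB1, encoding cyclin B1, by -0.69 ± 0.08, from 328 to 204 CPM. FAM83D, CENPA, KIF18A, GTSE1, HJURP, CDCA2 and CKS2 completed the 10 lowest, with changes from -0.99 for FAM83D to -0.64 for CKS2. Of 16 alternative settings, the call of CKS2 was lost in 8, that of CDCA2 in 7, GTSE1 and HJURP in 4, KIF18A and CCNB1 in 3 and FAM83D in 1. Of the 35 G2 and mitosis genes 9 fell, 32 when adjusted over the list alone, with a median of -0.41 (camera adjusted p = 5.4e-80; adjusted p = 0.0080 with an estimated correlation; fry adjusted p = 0.0011). MUC1, a membrane mucin on chromosome 1 at 155185824 to 155192916, rose from 8.48 to 13.5 CPM, a change of 0.67 ± 0.11 (adjusted p = 0.043), a call lost in 9 of 16 alternative settings. The other feature that rose, PDE8B, was named after its values were seen; it had 0 counts in both LBP libraries and was at least 19.1-fold higher in irradiated LBP libraries against a floor of 3 counts per library, or at least 9.54-fold if both mates were counted.

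None of the 31 p53 targets passed in irradiated LBP cells either way (camera adjusted p = 0.34), with CDKN1A at 0.37 ± 0.21 and MDM2 at 0.21 ± 0.08. Camera called 18 of 28 lists, of which the G2 and mitosis list alone held with an estimated correlation. When adjusted over the list alone, 11 of 18 heat shock genes fell (camera adjusted p = 4.9e-12; adjusted p = 0.19 with an estimated correlation), as did 16 of 33 ribosomal protein genes (adjusted p = 1.7e-17; 0.39 with an estimated correlation) and 14 of 30 respiratory chain genes (adjusted p = 2.2e-11; 0.42 with an estimated correlation), and none of these passed over all genes. With the length trend removed the medians of the ribosomal and respiratory lists went from -0.23 and -0.18 to -0.072 and -0.035. The mitochondrially encoded genes were called higher (median 0.38, adjusted p = 2.7e-06; 0.48 with an estimated correlation). So were the NF-kB (adjusted p = 2.7e-06; 0.49 with an estimated correlation), immediate early (4.1e-07; 0.48 with an estimated correlation) and ERK lists (0.00046; 0.48 with an estimated correlation). The other 10 lists called, among them the NRF2 genes on the lower side, had a camera adjusted p from 0.00042 to 0.039 (adjusted p from 0.42 to 0.63 with an estimated correlation), and none of their members passed over all genes.

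In total 21 features changed after irradiation with LBP, 2 higher and 19 lower, and 5 changed by at least 2-fold. At an unadjusted p under 0.05 there were 2003, where chance alone gives a share of 0.05 of the 14799 tested. All 21 had groups that did not overlap, against 28.04% of all genes, where chance gives 20%. The split was 80 higher and 104 lower with DESeq2, 184 in total; the count was 45 without a filter on low counts, 10 with only these 2 groups in the model, 10, 10 and 7 with limma on the FPKM values, and 35 with the length trend removed. It was 8 without LBP replicate 2, 33 and 51 without irradiated LBP replicate 1 or 2, and 9 without both LBP replicate 2 and irradiated vehicle replicate 3.

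The interaction asked whether the effect of LBP differed between irradiated and non-irradiated cells. By edgeR 2 features passed, PDE8B and AC008982.1. Both fall outside the naming rule because of their low levels and were named after their values were seen. PDE8B, a cyclic AMP phosphodiesterase gene, had 0 counts in both LBP libraries and 0.86 to 1.47 CPM in the other 8 (adjusted p = 0.0044). AC008982.1 had 0 counts in both vehicle libraries and all 3 irradiated LBP libraries and 0.42 to 0.72 CPM in the other 5 (adjusted p = 0.0061). Each overlaps another gene on its strand. DESeq2 called 16 features, 6 higher and 10 lower, against 1 and 1 with edgeR. By edgeR 1213 had an unadjusted p under 0.05, where chance alone gives a share of 0.05 of the 14799 tested. The count of calls was 7 without a filter on low counts, both reported features among them. It was 0 with a mean CPM of at least 1. Limma on log2(FPKM + 1) and log2(FPKM + 0.1), with a mean FPKM of at least 1, gave 0 and 1. Neither reported feature was tested in these settings, so the counts do not bear on them. With the length trend removed the count was 1, the only reported feature tested there. With the replicate number as a block the count was 1, also a reported feature. It was 0 without LBP replicate 2, 4 without irradiated vehicle replicate 2, 5 without irradiated LBP replicate 1 and 0 without both LBP replicate 2 and irradiated vehicle replicate 3.

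For HMOX1, CYP1A1 and CXCL6 the interaction was not called (adjusted p = 0.645, 0.715 and 0.917). Their LBP changes were 4.24 ± 0.20 and 4.75 ± 0.25 for HMOX1, 3.18 ± 0.15 and 2.87 ± 0.18 for CYP1A1, and -1.44 ± 0.12 and -1.35 ± 0.14 for CXCL6 in irradiated and non-irradiated cells. The 2 LBP comparisons share no library. In them 68 features rose in both, where independent lists of these sizes give 2.23, and 23 fell in both, where they give 0.611. Of the 119 features called in non-irradiated cells 114 had the same sign in irradiated cells, and 1 was called in opposite directions. Across all genes, which are not independent replicates, the Spearman correlation of the LBP effects was 0.32 (jackknife SE 0.15) and the Pearson correlation 0.12. For the irradiation effects with and without LBP, 17 features fell in both, where independent lists give 0.077, and none rose in both, where they give 0.00068. Of the 65 features called without LBP 61 had the same sign with LBP, and 1 was called in opposite directions. The Spearman correlation across all genes was 0.090 (jackknife SE 0.16) and the Pearson correlation -0.013.

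**Figure D3:**
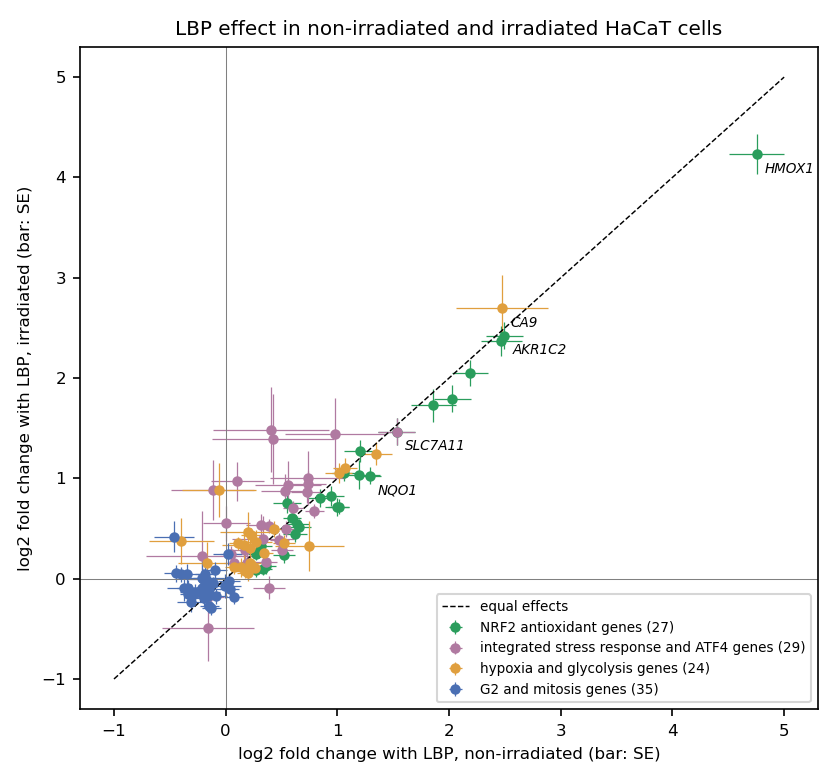
Log2 fold changes with LBP in non-irradiated cells (horizontal axis) and irradiated cells (vertical axis) for the tested genes of 4 lists, with bars for the SE and a dashed line of equal effects. The NRF2 genes lie to the upper right, with medians of 0.94 and 0.76, and the G2 and mitosis genes lie near 0, with medians of -0.20 and -0.10.

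Whether LBP turned back the changes made by irradiation was examined in the 65 features called for irradiation without LBP. Of these, 35 (53.8%, exact binomial interval 41.0 to 66.3%) had the opposite sign with LBP in irradiated cells. The interval takes the features as independent, which they are not, so it does not measure the spread between libraries. The irradiated vehicle libraries stand on opposite sides of these comparisons, which alone gives opposite signs. In 50 simulations of unchanged groups the share was 90.1% on average (81.5 to 98.5%), but these leave out real irradiation changes and take genes by chance values of the shared libraries, so they are no measure for the 65 calls. Of the 65, 3 were called in the opposite direction with LBP, where independent lists give 1.75, and none in the same direction. The 60 that fell had a median of -0.68 after irradiation and of -0.00070 with LBP in irradiated cells, and the median of their interaction was 0.18. These features were chosen by a low value of irradiation without LBP, which enters the interaction with the opposite sign. A positive median of the interaction can therefore follow from that choice alone and is no measure of a weaker irradiation effect with LBP. Over all genes the covariance of the effects was -0.087, against -0.037 (SD 0.0047) in the simulations, a difference of -0.050. The Pearson correlation was -0.42, against -0.43 in the simulations. The simulations hold no real effects of LBP or irradiation, which can change both measures. Neither comparison with them can therefore decide on a reversal, and the difference in covariance is not taken as one. The 3 irradiated vehicle libraries are too few to be split into sets of at least 2, so part of any excess may come from sharing them. Without irradiated vehicle replicate 3 the share of opposite signs, among the features called in that fit, was 37.1%, outside the binomial interval.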

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

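Of the tests in this part, the overlap of genes with others on the same strand was chosen after the result was seen, as was the setting without the libraries with the most negative length trends; the removal of the length trend was added after the data were seen, with its predictions written before its results.

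The effect of LBP differed between irradiated and non-irradiated cells for 2 features by edgeR's interaction test with Benjamini-Hochberg adjustment. PDE8B (adjusted p = 0.00441) had 0 counts in both LBP libraries and from 0.86 to 1.47 CPM in the other 8, so that it was at least 12.8-fold lower with LBP in non-irradiated cells (at least 6.38-fold if both mates of each read pair were counted). AC008982.1 (adjusted p = 0.00611) had 0 counts in both vehicle and all 3 irradiated LBP libraries, so that it was at least 8.34-fold lower with LBP in irradiated cells and at least 7.45-fold higher in non-irradiated cells, all against 3 counts per library. If both mates were counted, the bounds for AC008982.1 are 4.17-fold and 3.72-fold.

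Such switches between nothing and a clear level were seen in other genes, and a candidate explanation is that reads were assigned to a different member of a group of overlapping genes in some libraries. Of tested genes, 25 had at most 3 counts in at least 2 libraries and at least 100 in at least 2 others. All 21 of them with a position (100%) overlap another gene on the same strand, against 11.5% of the other tested genes (Fisher's exact test, two-sided, p = 2.1e-20). PDE8B and AC008982.1 themselves fall in a wider set, with at least 20 counts in place of 100 and also chosen afterwards, of which 52 of 66 with a position (78.8%) overlap a gene on the same strand, against 11.3% (Fisher's exact test, p = 1.8e-36). PDE8B overlaps AC022414.1, and AC008982.1 overlaps ECH1 and HNRNPL; the wider set holds 4, 2, 4, 3 and 2 of the features called for irradiation without LBP, LBP in irradiated cells, LBP in non-irradiated cells, irradiation with LBP and the interaction, and a change of these genes in the cells was not tested apart from read assignment.

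Camera called 9 lists for the interaction, none of which held with an estimated correlation (adjusted p = 0.83 for each) or with fry. The median difference was 0.11 for the G2 and mitosis genes (camera adjusted p = 0.0028), -0.071 for the S phase genes (0.0075), -0.13 for the NRF2 genes (0.0028), -0.16 for the heat shock genes (0.0026), -0.22 for the activation keratins and alarmins (0.021) and 0.12 for the cholesterol genes (0.023). It was -0.23 for the cytosolic ribosomal protein genes (2.7e-13), -0.22 for the nuclear respiratory chain genes (1e-09) and 0.46 for the mitochondrially encoded genes (6.0e-07). Without irradiated LBP replicate 2 camera called 15 lists, and without both libraries with the most negative length trends it called 5.

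The lower ribosomal and respiratory chain lists in the interaction may come from the trend on gene length. Transcripts of these lists have median lengths of 1097 and 1209 bases, against 3515 over all genes. With the length trend removed, the median of the ribosomal list went from -0.23 to -0.013 (camera adjusted p = 0.010, and 0.75 with an estimated correlation) and that of the respiratory list from -0.22 to -0.030 (camera adjusted p = 0.17). The mitochondrially encoded genes, which are also short, went the other way, from 0.46 to 0.65, so the length trend does not account for them. Medians also shrank for the NRF2 genes to -0.047 (camera adjusted p = 0.086) and for the activation keratins and alarmins to -0.066 (camera adjusted p = 0.25). For the heat shock genes the median shrank to -0.073 (camera adjusted p = 0.030). Those of the G2 and mitosis (0.14), S phase (-0.075) and cholesterol genes (0.15) did not shrink. A joint effect of LBP and radiation on these lists stays open, since no test here separates it from differences between libraries.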

How the results depend on the processing

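Removal of the length trend and leaving out LBP replicate 2 with irradiated vehicle replicate 3 were chosen after the data were seen. Counts of changed features are given in the order irradiation without LBP, LBP in irradiated cells, LBP in non-irradiated cells, irradiation with LBP and interaction, where the reported counts are 65, 645, 119, 21 and 2. With RLE factors they stayed within 1.5 times. DESeq2 gave 129, 1228, 374, 184 and 16 and called 63, 636, 119, 19 and 2 of the reported features. Models with only the groups compared gave 109, 409, 278 and 10, with none fitted for the interaction. Limma on log2(FPKM + 1) with a mean FPKM of at least 1 gave 43, 388, 84, 10 and 0, on log2(FPKM + 0.1) it gave 42, 382, 79, 10 and 1, and on every feature with any FPKM 21, 169, 45, 7 and 3. With no filter on low counts there were 79, 713, 188, 45 and 7, and with a mean CPM of at least 1 there were 65, 708, 132, 19 and 0 by edgeR. The 2 interaction features were not tested with a mean CPM or a mean FPKM of at least 1, so the interaction counts there do not bear on them. A 2-fold minimum left 14, 77, 42, 5 and 2. Removal of the length trend gave 75, 856, 137, 35 and 1, and leaving out the 2 libraries together gave 32, 150, 34, 9 and 0. Leaving out 1 replicate at a time gave 25 to 35, 176 to 722, 38 to 52, 8 to 51 and 0 to 5. A group left with 1 library was assumed to vary like the others. Fewer libraries were tested in these settings; for the other settings the cause was not tested. Beside each interaction count of 0, 1213 features had an unadjusted p under 0.05 in the reported fit. Chance alone gives a share of 0.05 of the 14799 tested.

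With the replicate number as a block there were 56, 813, 148, 31 and 1. The correlations of deviations for the same-numbered irradiated vehicle and irradiated LBP libraries were 0.030, -0.077 and 0.107. Not every library correlated best with its own number. Deviations from means of so few libraries can neither show nor exclude a shared culture or day.

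Of the reported calls that were tested, each kept its sign in each of these settings, except 1 feature for LBP in irradiated cells with limma. Of 121 calls followed by gene, 51 were kept in every setting other than the 2-fold minimum, among them AURKA, CCNF and PIF1 after irradiation without LBP and HMOX1, CYP1A1, CYP1B1, NQO1, SLC7A11 and CXCL6 in both LBP comparisons. Over 2874 values of genes followed singly, which include the 2-fold minimum, 492 lost a call, 12 gained 1, none reversed, and 41 without a call moved by more than the spread between libraries. Camera called 9, 14, 12, 18 and 9 lists, with an estimated correlation 1, 1, 1, 1 and 0, and fry called 2, 3, 2, 1 and 0. Leaving out a replicate gave 9 to 12, 10 to 14, 10 to 12, 13 to 19 and 6 to 15 lists, and leaving out the 2 libraries together gave 5 for the interaction. With a replicate left out, the share of opposite signs, for reversal of irradiation changes by LBP, was 37.1% (without irradiated vehicle replicate 3) to 62.2%. The Spearman correlation for agreement of the irradiation effect with and without LBP ran from -0.00389 to 0.181, and that for agreement of the LBP effect with and without irradiation from 0.207 to 0.366. Features of low level, such as CA9 and CXCL10, rest on few counts in the group with the lower level.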

Other observations

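The tests of other cell types and of aryl hydrocarbon receptor genes, and the genes named in the opening paragraph, were chosen after the results they bear on were seen.

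Further genes outside the fixed lists rose with LBP. TXNIP, which restrains glucose uptake and binds thioredoxin, changed by 1.18 ± 0.11 in irradiated and 0.91 ± 0.14 in non-irradiated cells, and its relative ARRDC4 by 0.88 and 0.83. SLC30A1, a zinc exporter, changed by 1.01 and 1.02. UGT1A6, a glucuronosyltransferase, changed by 0.45 and 0.64, and it overlaps UGT1A1 on its strand. TIPARP, a target of the aryl hydrocarbon receptor, rose by 0.61 in irradiated cells and stood at 0.56, not called, in non-irradiated cells.

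The number of genes called with LBP in irradiated cells was set against other splits of the 6 irradiated libraries. With these 6 alone the real split called 409 genes, and the highest of the other 9 splits called 1, so 1 of the 10 splits gave as many. With 10 splits the share cannot go under 0.1, which is too few to exclude chance.

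The hypothesis that LBP activates NRF2 may account for the rise of 23 of the 27 listed genes, and it was set against 3 other explanations. Removal of the length trend left 24 of the 27 called higher in irradiated cells, with a median of 0.80, so that trend is not the whole cause. Summed markers of other cell types rose by at most 3.97 CPM, for fibroblast markers, with 3.28 CPM for leukocyte, -0.44 for endothelial and -2.02 for melanocyte markers, against a rise of NQO1 from 258 to 526 CPM; the most abundant of these markers were FBLN1 (27.7 CPM) and CD68, with MITF at 6.84 CPM and COL1A1 at 4.76 CPM. Metal in the preparation would raise metallothionein genes, but the medians of the 4 tested were -0.044 in irradiated and 0.27 in non-irradiated cells, although the rise of SLC30A1 goes with metal. What remains is a hypothesis, since NRF2 activity itself was not measured and other contents of the preparation were not tested.

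The rise of CYP1A1 and CYP1B1 could come from aryl hydrocarbon receptor activity. The other 6 tested genes of that receptor's battery had a median of 0.53 in irradiated cells, above all 10000 random lists of matched expression, and 3 of them were called. Because AHRR lies near the floor and 1 library sets its value, a limit on level was added after this value was seen; over the remaining 5 genes the median was 0.45, also above all 10000 random lists but under the 0.5 set as the bar. That median is the value of UGT1A6, which overlaps UGT1A1 on its strand, so how its reads were divided is uncertain. ALDH3A1, UGT1A6 and NFE2L2 are also tied to NRF2, so the contribution of the 2 pathways cannot be told apart with these genes.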
